A study of Homo sapiens with 6 samples.

How the data were processed

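The data are 6 RNA-seq libraries of A375 melanoma cells, 3 labelled PAL and 3 labelled control, with groups and replicate numbers taken from the sample titles. Total RNA was extracted with a column kit and enriched for poly-A, per the labels' protocols. The genome build hg38 is listed in the submitters' processing notes. The aligner, the counting tool and whether strand was used are not given in the sources used here. The deposited table gives 1 FPKM value per gene and library for 58735 genes, with a gene length, biotype and position, per the file headers. All 58735 genes have the same start and end in GENCODE release 29.

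The FPKM values as deposited are reads scaled by gene length and by a library size. Each value times the gene length was a whole multiple of 1 step per library: 100% of values above 0 lay within 0.01 of a whole number of reads, so reads per gene and the depth were recovered. The depth was 15064971 to 17711389 assigned reads per library. The library size behind the FPKM was not the plain total but 0.980 to 0.984 of it in control libraries and 1.04 to 1.05 of it in PAL libraries, and stood at 0.9993 to 1.0008 of the size from median-of-ratios factors. Intervals and floors that rest on reads cover counting error only, since reads amplified by PCR are not independent molecules. For a gene with no reads in a group, the floor was 3 reads over the group.

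Genes with an FPKM of at least 1 in at least 3 libraries were tested, 12258 in all. The test was limma 3.58.1 in R 4.3.3, a linear model of log2(FPKM + 1) with a moderated variance that follows expression, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, PAL minus control, which understates the change of low genes. Each group has 3 libraries and the fit has 4 residual degrees of freedom.

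In total 40 gene lists were fixed before the data were examined, and 909 of their 911 entries were matched to genes in the table by current or older symbol. The 35 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the lists, beside camera with an estimated correlation and fry. Counts per list are given over all genes tested and adjusted over the list alone. Genes named in the text follow a rule fixed at the same time. It takes the 10 largest rises and 10 largest falls among protein-coding genes that passed, did not overlap between groups and had a mean of at least 5 FPKM in the higher group. It adds up to 2 rises and 2 falls per list, or the 2 highest members where none passed, and a fixed set of chaperone, stress and death genes. It gave 135 genes, of which part are named, and genes outside it are marked as such.

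On simulated reads with known changes over 12239 tested genes, drawn from the means and depths of the PAL and control libraries, the fit called 36% of genes changed 1.25-fold, 82% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, out of 50 each. Of its calls, 9.20% were unchanged genes, which is above the nominal 5%. The spread between simulated replicates came from an assumed formula and was not estimated from these libraries. Far fewer genes were changed than were called in the real data, so these rates need not hold there. A raised list was called, and 0 of 20 unchanged lists were.

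No pair of replicates agreed within counting noise: chi-square per degree of freedom was 1.97 to 3.99 within groups, and 33.1 to 40.5 between groups. Alternatives covered the pseudocount (0.1 and 0.5), the filter, the scaling, protein-coding genes only, the variance model, a replicate block, a fold threshold, voom (limma's model of read counts with weights) on the recovered reads, and leaving out each library. Added after seeing the data were scaling by plain read totals and leaving out both libraries numbered 3. Figures were drawn with matplotlib 3.10.9.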

Results

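Poly-A enriched RNA was sequenced from A375 cells, a human malignant melanoma cell line, kept with or without PAL, a Ringer's lactate solution activated with low-temperature plasma. The 6 libraries formed 2 groups, PAL and control, of 3 libraries each. Reads assigned to genes ranged from 15064971 in control replicate 2 to 17711389 in PAL replicate 3. Dose, exposure time and culture conditions are not given in the sources used here, and neither is whether the replicates came from separate cultures. The column names of the PAL libraries alone carry the number 64, whose meaning is not given in the sources used here. The limma p-values of single genes therefore measure the spread between these libraries, which may be technical. Camera at the preset correlation compares the genes of a list with the other genes, so its p-values measure a spread over genes. Fisher and permutation tests below also run over genes. Gene positions are those of hg38, and values are mean FPKM ± SD over 3 libraries unless stated.

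The comparison of PAL with control asked which transcripts differ with the treatment. The largest differences were falls in genes of stress responses. HSPA6, a stress-inducible HSP70, stood at 1882 ± 171 FPKM in control and 40.4 ± 28.6 in PAL, and HSPA1A, another inducible HSP70, at 1386 ± 25.4 and 65.3 ± 26.1. By mean FPKM in control, HSPA6 ranked 8 of 12258 tested genes, so stressed control cells or exchanged labels stay open, as set out further below. FOSB, a transcription factor of the immediate early response, stood at 64.7 ± 6.96 and 2.31 ± 1.33. Rises were smaller. CLK2, a kinase of splicing factors, had the largest rise among the protein-coding genes that passed, did not overlap between groups and reached a mean of at least 5 FPKM, from 7.43 ± 0.635 to 13.7 ± 0.613 FPKM.

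Of 12258 genes tested with limma, 3179 (25.9%) differed at an adjusted p below 0.05, 1399 higher and 1780 lower in PAL. On the log2(FPKM + 1) scale, changes of at least 2-fold made up 17 of the rises and 194 of the falls, and 40 genes fell at least 4-fold while 0 rose as much. This scale understates low genes: HIST1H4E, a histone, rose with a ratio of means of 4.36 from 0.291 FPKM. It passed the filter through the PAL libraries alone, so that ratio rests on a low control value. The 211 genes changed at least 2-fold became 336 with voom on the recovered reads and 128 with a mean of at least 5 FPKM. The values of both groups did not overlap for 5508 genes (44.9%), against 10% by chance. The count of changed genes dropped to 1972 without PAL replicate 1, 1855 without PAL replicate 2 and 2051 without control replicate 2. The share of rises among the calls depended on the scaling: 44.0% with the values as deposited, 59.2% after quantile normalization, 69.7% as TPM and 73.3% when each library was scaled by its plain total of reads.

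**Figure D1:**
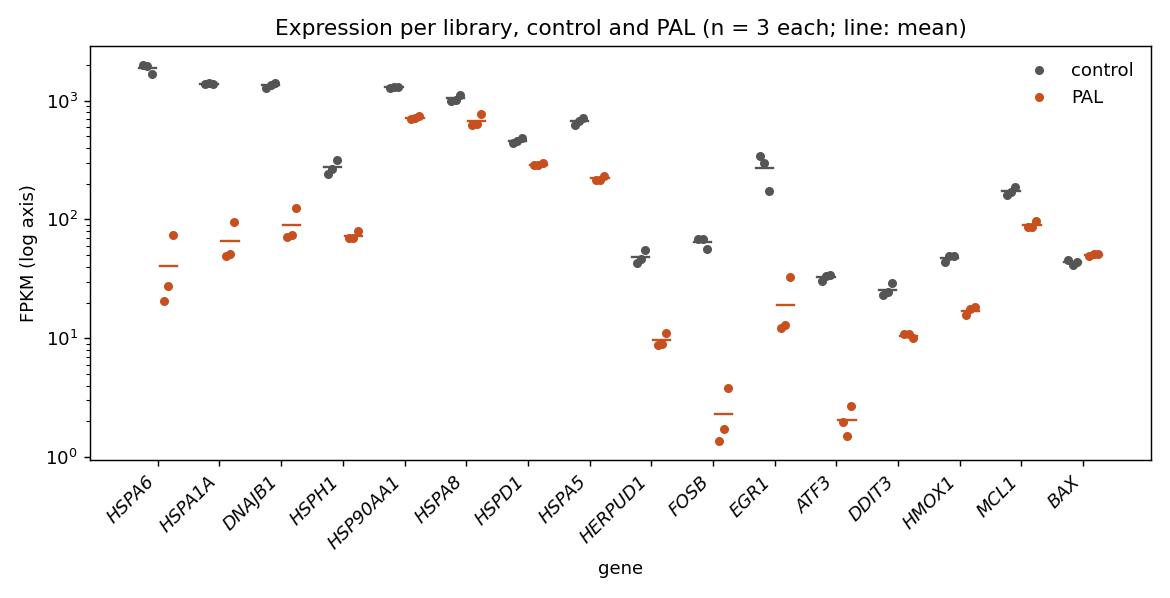
FPKM of 16 named genes in each library on a log axis, with control libraries in grey, PAL libraries in orange and a line at each group mean (n = 3). HSPA6 lies at 1882 FPKM on average in control and at 40.4 in PAL, whereas BAX lies at 43.5 in control and 50.3 in PAL.

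Heat shock proteins and their co-chaperones fell together. Of 34 tested members of the heat shock list, 28 were lower in PAL and 0 higher, and 29 were lower when adjusted over the list alone. For lists below with no such second count, it was the same. Camera asks whether a list differs from other genes. In contrast, fry asks whether the members changed on average in 1 direction, without a comparison to other genes. It can therefore pass where members lie on both sides. Ranges over alternatives leave out fry and the estimated correlation. The series title names the direction of this group, so the count is not independent evidence of it. HSPA6 (chromosome 1, 161524540 to 161526910) fell by 5.71 ± 0.41 (SE) on the log2 scale, with an adjusted p of 1.79e-04 in limma. Its ratio of means was 46.5, and ranged from 37.4 without PAL replicate 1 to 78.3 without PAL replicate 3 when 1 library was left out. HSPA1A (chromosome 6, 31815464 to 31817946) fell by 4.45, HSPA1B (chromosome 6, 31827735 to 31830255) by 4.43 and DNAJB1, an HSP40 co-chaperone (chromosome 19, 14514770 to 14529770), by 3.93. HSPA1A and HSPA1B are near-identical, as are HSPA6 and its relative HSPA7 in part, so the split of reads within each pair is uncertain. Other chaperones of the list had smaller falls. HSP90AA1 went from 1300 ± 16.3 to 716 ± 27.4 FPKM, HSPH1 from 274 ± 37.2 to 72.9 ± 5.71, HSPA8 from 1041 ± 66.7 to 674 ± 79.3 and HSP90AB1 from 1333 ± 11.4 to 1023 ± 6.32. The list took 4.09% ± 0.0882 of assigned reads in control and 1.69% ± 0.102 in PAL (n = 3 each). As a set it was lower by camera, a limma test of a list against the other genes (adjusted p = 3.49e-19, median log2 fold change -0.78), with an adjusted p = 0.259 with an estimated correlation between genes.

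PAL replicate 3 stood nearer to the control libraries in these genes: HSPA6 was at 20.7, 27.4 and 73.2 FPKM in PAL replicates 1, 2 and 3. With both libraries numbered 3 left out, a choice made after seeing the data, 25 of the 34 heat shock members were lower in PAL, and 1 was higher. The higher one was HSF1, the main heat shock transcription factor, named after its values were seen.

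Immediate early genes, which encode transcription factors and signalling regulators induced within minutes of a stimulus, fell almost throughout. In PAL, 24 of 25 were lower and 0 higher, the same counts when adjusted over the list alone. FOSB (chromosome 19, 45467995 to 45475179) fell by 4.38, EGR1 (chromosome 5, 138465490 to 138469315) by 3.84, IER5 by 3.54 and EGR3 by 3.26 on the log2 scale. The camera adjusted p was 3.49e-19 and the adjusted p = 0.259 with an estimated correlation. These genes also varied within groups: FOS, named after its values were seen, was at 94.9, 75.9 and 32.8 FPKM in control replicates 1, 2 and 3 and at 9.60, 10.5 and 23.9 in PAL replicates 1, 2 and 3. Without the libraries numbered 3, 23 of the 25 were lower. DUSP5, a phosphatase of the ERK pathway, went from 67.1 ± 5.45 to 14.3 ± 2.03 FPKM, while the list of ERK output genes did not differ from other genes as a set (2 of 18 higher, 3 lower, 4 and 3 when adjusted over the list alone, camera adjusted p = 0.726, fry adjusted p = 0.0340).

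Among NF-kB targets, 14 of 17 tested were lower and 0 higher (15 lower when adjusted over the list alone), and 13 were lower without the libraries numbered 3. TNFAIP3, an inhibitor of NF-kB signalling, went from 18.1 ± 0.758 to 2.45 ± 0.435 FPKM and NFKBIA, another such inhibitor, from 29.3 ± 4.21 to 8.25 ± 2.10. The set was lower by camera (adjusted p = 9.00e-09), with an adjusted p = 0.259 with an estimated correlation. Interferon-stimulated genes did not differ from other genes as a set (1 of 12 higher, 2 lower, camera adjusted p = 0.141, fry adjusted p = 0.00284), but passed with camera as lower with no filter (adjusted p = 0.0418, range 0.0418 to 0.585 over 17 alternatives). IRF1 fell from 5.78 ± 0.460 to 1.81 ± 0.0865 FPKM.

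Genes of the endoplasmic reticulum and of the integrated stress response fell as well. Of 19 tested endoplasmic reticulum chaperones and unfolded protein response genes, 14 were lower and 0 higher (16 lower when adjusted over the list alone), and 14 were lower without the libraries numbered 3. HSPA5, the HSP70 of this compartment, went from 669 ± 44.8 to 221 ± 10.9 FPKM and HERPUD1 from 48.4 ± 6.50 to 9.60 ± 1.24. Of 23 tested targets of ATF4, 12 were lower and 2 higher (14 and 2 when adjusted over the list alone), and 13 were lower and 1 higher without the libraries numbered 3. ATF3, also in the immediate early list, went from 32.7 ± 1.92 to 2.05 ± 0.592, CHAC1 from 18.7 ± 0.887 to 3.17 ± 0.0242 and DDIT3, which encodes CHOP, from 25.6 ± 3.18 to 10.5 ± 0.416. The 2 that rose were PCK2 and SLC7A5, by 0.25 and 0.22 on the log2 scale. The call of PCK2 was lost without PAL replicate 1 (adjusted p = 0.0744), PAL replicate 2 (adjusted p = 0.0636) or control replicate 1 (adjusted p = 0.0536), over a range of 0.00759 to 0.0744 in 20 alternatives. Camera gave an adjusted p of 1.09e-08 for the first list and 1.83e-06 for the second. With an estimated correlation, the adjusted p = 0.368 for the first and the adjusted p = 0.259 for the second.

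HIF targets of the hypoxia list were lower in 10 of 14 cases and higher in 0 (12 lower when adjusted over the list alone, camera adjusted p = 3.09e-06, adjusted p = 0.259 with an estimated correlation), and 7 were lower without the libraries numbered 3. ANKRD37 went from 7.98 ± 0.536 to 1.79 ± 0.234 FPKM and ADM from 32.9 ± 5.28 to 10.5 ± 1.57. The glucose transporter SLC2A3 went from 19.2 ± 0.907 to 6.11 ± 0.369 FPKM, whereas the glycolysis list as a set did not pass (2 of 23 higher, 7 lower, 2 and 9 when adjusted over the list alone, camera adjusted p = 0.141, fry adjusted p = 2.84e-04). It passed with camera as lower with no filter (adjusted p = 0.0418, range 0.0418 to 0.716 over 17 alternatives). In sterol synthesis, 9 of 21 genes were lower and 1 higher (12 and 1 when adjusted over the list alone, camera adjusted p = 9.24e-04, adjusted p = 0.356 with an estimated correlation). HMGCS1, an early enzyme of that pathway, went from 27.4 ± 4.36 to 9.01 ± 0.386 FPKM, and LSS rose by 0.18 on the log2 scale, a call lost without PAL replicate 1 (adjusted p = 0.0577, range 0.00384 to 0.0651 over 20 alternatives).

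Genes of cell death did not move one way. In the list of pro-apoptotic genes, 2 of 23 were higher and 5 lower (4 and 6 when adjusted over the list alone), and the set did not pass (camera adjusted p = 0.539). FADD, an adaptor of death receptors, rose from 27.8 ± 1.93 to 38.5 ± 1.73 FPKM and BAX from 43.5 ± 2.12 to 50.3 ± 1.28. The call of BAX was lost without both libraries numbered 3 (adjusted p = 0.0615, range 0.00115 to 0.0615 over 20 alternatives). PMAIP1, which encodes NOXA, fell from 46.1 ± 0.141 to 21.5 ± 2.23 and BBC3, which encodes PUMA, from 3.05 ± 0.116 to 1.72 ± 0.393. In the anti-apoptotic list, 2 of 12 were higher and 4 lower (camera adjusted p = 0.402, fry adjusted p = 0.0258). MCL1 fell from 173 ± 14.4 to 89.5 ± 5.71 FPKM. BCL2L1 stood at 19.6 ± 0.884 and 20.6 ± 0.611, which did not pass in limma (adjusted p = 0.288), but passed after scaling to TPM (adjusted p = 0.0457) or to plain read totals (adjusted p = 0.0290), over a range of 0.0290 to 0.624 in 20 alternatives. Of 22 tested p53 targets, 8 were lower and 3 higher (9 and 3 when adjusted over the list alone), with GADD45A, BTG2 and CDKN1A lower by 1.46, 1.72 and 0.51 on the log2 scale and MDM2, AEN and BAX higher by 0.26, 0.23 and 0.21. Of these, BTG2 is also in the immediate early list. The p53 list passed narrowly as lower (camera adjusted p = 0.0455, adjusted p = 0.424 with an estimated correlation). It did not pass without PAL replicate 1 (adjusted p = 0.0604), PAL replicate 2 (adjusted p = 0.0542) or control replicate 3 (adjusted p = 0.131), over a range of 0.00695 to 0.131 in 17 alternatives.

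Antioxidant genes did not differ from other genes as a set. Of 25 tested NRF2 targets, 5 were lower and 1 higher (3 and 1 when adjusted over the list alone, camera adjusted p = 0.496, fry adjusted p = 0.0268). HMOX1, heme oxygenase 1, went from 47.5 ± 3.47 to 17.1 ± 1.35 FPKM, a fall of 1.42 on the log2 scale (limma adjusted p = 4.06e-05), and GCLC from 8.29 ± 0.194 to 6.06 ± 0.224. FTH1, ferritin heavy chain, rose from 1565 ± 16.2 to 1701 ± 57.5, a call lost without PAL replicate 2 (adjusted p = 0.0768) or 3 (adjusted p = 0.0596) or without control replicate 1 (adjusted p = 0.0785) or 2 (adjusted p = 0.0656). Its adjusted p ranged from 4.51e-04 to 0.182 over 20 alternatives. Of 17 enzymes that remove peroxide or superoxide, 4 were lower and 0 higher (4 and 1 when adjusted over the list alone, camera adjusted p = 0.824). In the ferroptosis list, 1 of 15 was higher and 6 were lower (2 and 6 when adjusted over the list alone, camera adjusted p = 0.172, fry adjusted p = 2.84e-04).

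**Figure D2:**
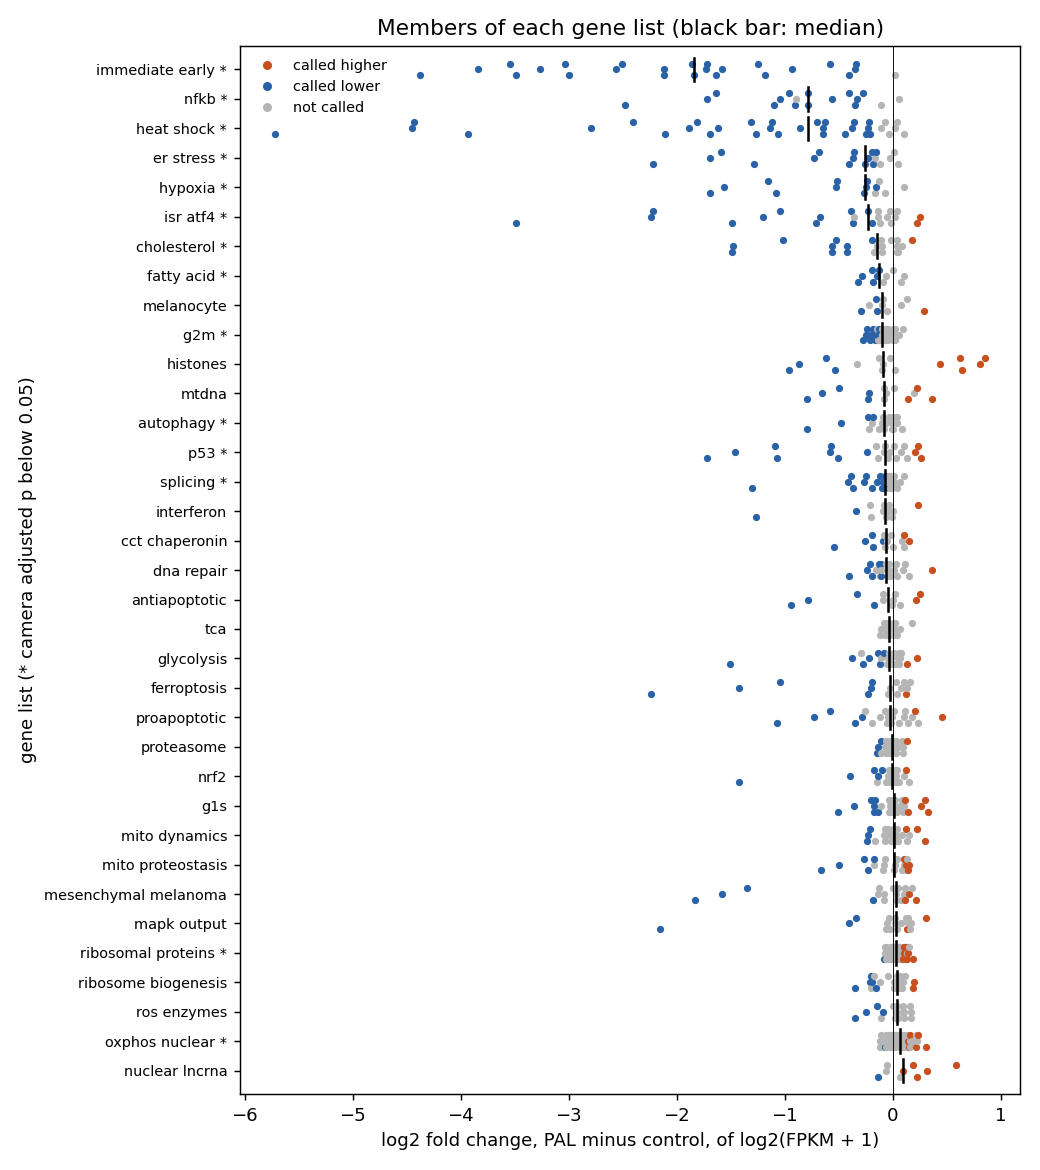
Log2 fold change (PAL minus control, of FPKM plus 1) of each tested member of the 35 tested lists, with members called higher in orange, lower in blue and not called in grey, the median of each list as a black bar and a star where camera passed. The immediate early list has the lowest median, -1.84, and the heat shock list lies at -0.78.

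Mitochondrial genes named in the question of the study changed in several ways. Among mitochondrial chaperones and proteases, 5 of 20 were lower and 4 higher (5 and 5 when adjusted over the list alone, camera adjusted p = 0.600, fry adjusted p = 0.00239). HSPD1, or HSP60, fell from 460 ± 23.2 to 289 ± 6.29 FPKM and its partner HSPE1 fell by 0.50 on the log2 scale. HSPA9, or mortalin, fell by 0.18 on the log2 scale, a call lost after quantile normalization (adjusted p = 0.0895) or scaling to plain read totals (adjusted p = 0.0502), over a range of 5.90e-05 to 0.0895 in 20 alternatives. Nuclear-encoded subunits of the respiratory chain and ATP synthase were higher as a set (median log2 fold change 0.07, camera adjusted p = 0.0237, adjusted p = 0.368 with an estimated correlation). In that list 6 of 55 genes were higher and 1 lower, and 2 and 0 when adjusted over the list alone. The set did not pass without PAL replicate 2 (adjusted p = 0.0583), over a range of 6.00e-05 to 0.0583 in 17 alternatives. NDUFS8 rose by 0.30. The lower one, ATP5F1B, fell by 0.07 (adjusted p = 0.0494) and turned after quantile normalization, where it passed as higher (0.13, adjusted p = 0.0307), and to 0.011 with plain read totals (adjusted p = 0.714). That call was also lost without PAL replicate 1 (adjusted p = 0.159), PAL replicate 2 (adjusted p = 0.122), or control replicate 1 (adjusted p = 0.147), 2 (adjusted p = 0.0936) or 3 (adjusted p = 0.0802), over a range of 0.0131 to 0.941 in 20 alternatives. Of 18 genes of the tricarboxylic acid cycle, 0 were called in limma (3 at an unadjusted p below 0.05) and 0 with voom on recovered reads (camera adjusted p = 0.509). MDH2 differed by 0.02 on the log2 scale (limma adjusted p = 0.608), and passed as higher after scaling to TPM (adjusted p = 0.0344), over a range of 0.0169 to 0.883 in 20 alternatives. For fission, fusion and biogenesis genes, 3 of 25 were higher and 3 lower (camera adjusted p = 0.860), OPA1 and MFN1 fell by 0.24 and 0.23. The call of MFN1 was lost without PAL replicate 1 (adjusted p = 0.0531, range 0.00214 to 0.0670 over 20 alternatives).

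Transcripts of the mitochondrial genome moved in both directions. Of its 13 protein-coding genes, 3 were higher and 5 lower (4 and 5 when adjusted over the list alone), and the set did not pass (camera adjusted p = 0.288). MT-ATP6 (positions 8527 to 9207) went from 2030 ± 64.4 to 2611 ± 262 FPKM, a call lost with no filter (adjusted p = 0.0612, range 4.37e-05 to 0.0612 over 20 alternatives), and MT-CO1 (positions 5904 to 7445) from 2454 ± 62.7 to 1563 ± 104. MT-ND6 (positions 14149 to 14673) went from 209 ± 31.9 to 120 ± 11.7. MT-ND2 rose by 0.22, a call lost without PAL replicate 1 (adjusted p = 0.0553), control replicate 1 (adjusted p = 0.0782) or control replicate 2 (adjusted p = 0.0771), over a range of 4.86e-04 to 0.127 in 20 alternatives. Named after their values were seen, MT-ATP8 rose by 0.14 and MT-ND5, MT-ND4L and MT-CO2 fell by 0.50, 0.23 and 0.22, and both ribosomal RNAs were higher, MT-RNR1 by 0.98 and MT-RNR2 by 0.67. Reads of the mitochondrial genome made up 1.92% ± 0.0355 of assigned reads in control and 2.02% ± 0.104 in PAL (n = 3 each). Overlapping mitochondrial genes on opposite strands cannot be told apart if the counting ignored strand, which is not stated.

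**Figure D3:**
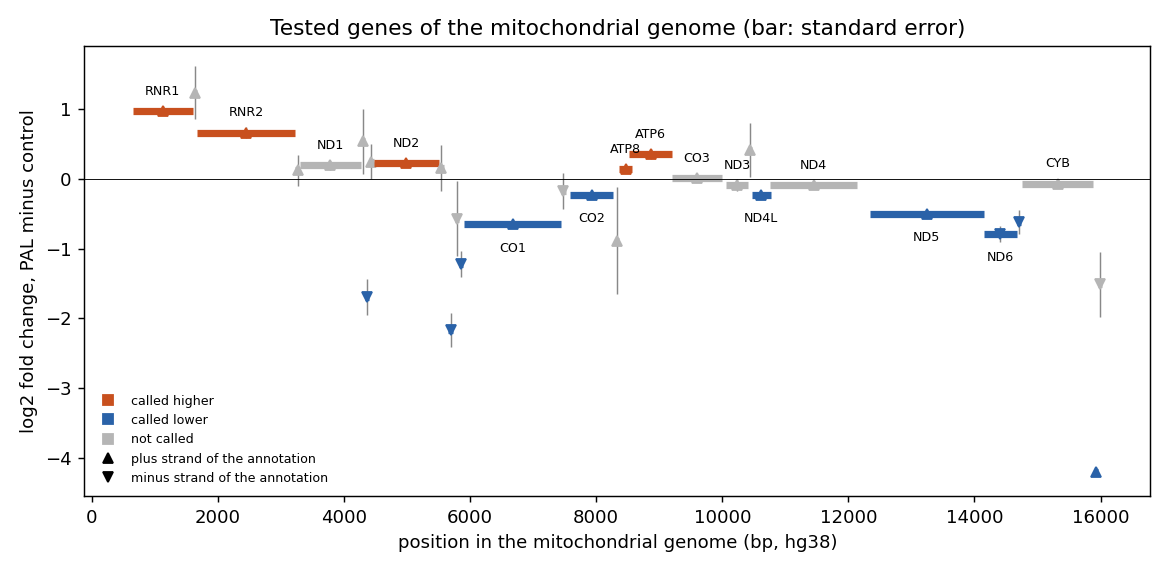
Log2 fold change (PAL minus control) of each tested gene of the mitochondrial genome at its position in bp, with thin bars for the standard error and triangles up or down for the plus or minus strand of the annotation. MT-RNR1 lies at 0.98 and MT-CO1 at -0.65, and the lowest point, MT-TT, had 0 reads in the PAL libraries, so that its fitted value is no bound.

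Mitotic genes were lower as a set (10 of 30 lower, 0 higher, camera adjusted p = 0.00135, adjusted p = 0.476 with an estimated correlation), and ANLN and CENPE fell by 0.28 and 0.25. The call of CENPE was lost without PAL replicate 2 (adjusted p = 0.0560, range 5.81e-04 to 0.0560 over 20 alternatives). The set did not pass after quantile normalization (adjusted p = 0.0568) or with plain read totals (adjusted p = 0.0564), over a range of 6.46e-06 to 0.0568 in 17 alternatives. G1/S genes did not differ from other genes as a set (5 of 28 higher, 7 lower, 5 and 8 when adjusted over the list alone, camera adjusted p = 0.819), nor did DNA repair genes (1 of 23 higher, 7 lower, 1 and 8 when adjusted over the list alone, camera adjusted p = 0.0682, fry adjusted p = 0.0151). The DNA repair list passed as lower without control replicate 3 (adjusted p = 0.0386), over a range of 0.00499 to 0.227 in 17 alternatives. Splicing factors were lower (13 of 24, 0 higher, 13 and 2 when adjusted over the list alone, camera adjusted p = 5.48e-04, adjusted p = 0.368 with an estimated correlation). CLK1 went from 11.3 ± 1.17 to 3.97 ± 0.555 FPKM. The median of that list, -0.08, turned to 0.0079 after quantile normalization and 0.0098 with plain read totals, and it did not pass there (adjusted p = 0.249 and adjusted p = 0.0751), over a range of 1.74e-06 to 0.249 in 17 alternatives. Cytosolic ribosomal proteins were higher as a set by a median of 0.03 (10 of 70 higher, 1 lower, 0 in either direction when adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.706 with an estimated correlation). That set did not pass without PAL replicate 2 (adjusted p = 0.0961) or control replicate 3 (adjusted p = 0.0513), over a range of 8.62e-14 to 0.0961 in 17 alternatives, and not with fry (adjusted p = 0.196). Fatty acid synthesis genes (6 of 11 lower, 0 higher, camera adjusted p = 0.0264) and autophagy genes (4 of 19 lower, 0 higher, camera adjusted p = 0.0319) were lower, each with an adjusted p = 0.261 with an estimated correlation. Neither passed after scaling to TPM (adjusted p = 0.0618 and adjusted p = 0.115), and autophagy genes did not pass without PAL replicate 2 (adjusted p = 0.0542). Over 17 alternatives the ranges were 0.00177 to 0.0762 and 0.00259 to 0.138. Not different from other genes as sets were chaperonin and prefoldin subunits (2 of 14 higher, 5 lower, 3 and 7 when adjusted over the list alone, camera adjusted p = 0.0939, fry adjusted p = 0.00146, but lower with no filter at an adjusted p = 0.0260, range 0.0260 to 0.955 over 17 alternatives), proteasome subunits (1 of 30 higher, 3 lower, camera adjusted p = 0.700) and ribosome biogenesis genes (2 of 23 higher, 5 lower, 3 and 7 when adjusted over the list alone, camera adjusted p = 0.860).

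Melanocytic genes did not differ from other genes as a set (1 of 10 tested higher, 3 lower, 1 and 4 when adjusted over the list alone, camera adjusted p = 0.509). SOX10, a transcription factor of this lineage, rose from 88.1 ± 1.68 to 108 ± 0.944 FPKM. Markers of undifferentiated melanoma states did not either (3 of 19 higher, 4 lower, 3 and 7 when adjusted over the list alone, camera adjusted p = 0.532, fry adjusted p = 0.00465), though CYR61 fell from 157 ± 8.87 to 43.7 ± 8.72 FPKM. Markers of other cell types were nearly absent: 4 of 14 keratinocyte, 1 of 11 fibroblast, 1 of 14 leukocyte and 0 of 9 endothelial markers reached the filter. SFN and KRT14 of the keratinocyte list were lower in PAL, 0 of the other markers were called, and 1 leukocyte marker was lower when adjusted over the list alone. KRT14 stood at 3.80 ± 0.424 and 2.87 ± 0.321 FPKM, and its call was lost without PAL replicate 1 (adjusted p = 0.122), PAL replicate 2 (adjusted p = 0.114), control replicate 1 (adjusted p = 0.0906) or control replicate 3 (adjusted p = 0.0986), over a range of 0.0174 to 0.122 in 19 alternatives. Too few of the 9 genes of the metallothionein list were tested for a set test, and 1 of the 3 tested was lower, the zinc transporter SLC30A1, which is not itself a metallothionein (1 lower and 1 higher when adjusted over the list alone). RNA-type lists did not differ from other genes as sets: replication-dependent histones (5 of 15 higher, 4 lower, camera adjusted p = 0.819) and nuclear long noncoding RNAs (5 of 9 higher, 1 lower, camera adjusted p = 0.0581, fry adjusted p = 0.00112). The nuclear list passed as higher after scaling to TPM (adjusted p = 0.0464) and without PAL replicate 1 (adjusted p = 0.0396), over a range of 0.0396 to 0.181 in 16 alternatives. NEAT1 rose from 2.96 ± 0.329 to 4.94 ± 0.150 FPKM.

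In all, 14 of the 35 tested lists passed with camera at its preset correlation, 12 lower and 2 higher. With an estimated correlation 0 passed, and 5 had an unadjusted p below 0.05, while fry called 24. Camera with an estimated correlation rests on the 4 residual degrees of freedom. There even the heat shock list, with 28 of 34 members lower, had an unadjusted p of 0.0370 and an adjusted p of 0.259. A failure in that form may therefore reflect the 3 libraries per group, and its power was not tested. Median, mean and test differed in sign for mitochondrial chaperones, G1/S genes, undifferentiated melanoma markers and ribosome biogenesis genes (median above 0, mean below 0 and test lower), and for ERK output and mitochondrial dynamics genes (median above 0, mean below 0 and test higher).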

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

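Scaling by plain read totals and leaving out both libraries numbered 3 were chosen after seeing the data, and the other alternatives before. Changed genes numbered 3179, and 2103 with no filter, where 29505 genes were tested, or 211 with a 2-fold minimum. Leaving out 1 library gave 1855 to 2789 changed genes, 688 to 1202 rises and 1167 to 1587 falls, with fewer samples, and 1801 to 2493 of the 3179 genes were called with the same sign. Without both libraries numbered 3, 2269 genes were changed. Rises numbered 765 with no filter, 2697 as TPM and 3097 with plain read totals, and falls 1170 and 1130, against 1399 and 1780. These 2 scalings moved the median of all genes to 0.07 and 0.08 on the log2 scale. Genes changed at least 2-fold numbered 128 with a mean FPKM of at least 5, where 6857 genes were tested, and 336 with voom on the recovered reads, against 211. With voom, 3001 of the 3179 genes were called with the same sign. With a replicate block, 838 rises and 2131 changed genes were called, and the lists called stayed at 14. The correlations of deviations between same-numbered libraries were -0.02, 0.03 and -0.04. They show no shared deviation, but cannot tell whether equal numbers shared a culture or a day. Lists changed numbered 14, 0 with an estimated correlation and 24 with fry, and 10 to 14 without 1 library. After quantile normalization and with plain read totals, ATP5F1B turned to 0.13 and 0.011, and RPL3 to 0.0046 and 0.0027. The median of the splicing list turned to 0.0079 and 0.0098, but its camera direction stayed lower, with the median of all genes at 0.032 and 0.075. The cause was not tested beyond the scaling itself. Of 135 named genes, 109 to 122 kept direction and side of the threshold in each run without 1 library, and in none of these did a called gene turn. Depth limits the low genes, such as mitochondrial tRNAs.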

Other observations

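Apart from the count over other splits of the libraries and the comparison of genomic spans, the tests here were chosen after the result was seen.

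Antisense and lincRNA genes had a larger share of rises than protein-coding genes with the values as deposited. Among antisense genes, 87 were higher in PAL and 14 lower, against 1198 and 1668 protein-coding genes (Fisher's exact test, two-sided, p = 1.95e-19), and among lincRNA genes 42 were higher and 21 lower (p = 9.20e-05). The balance of protein-coding genes turned with the scaling, to 2388 higher and 1069 lower as TPM and 2753 and 1031 with plain read totals, where antisense genes stood at 136 and 13 and at 146 and 13. With plain read totals the share of rises was 75.6% for lincRNA and 72.8% for protein-coding genes, so the lincRNA difference depended on the scaling. Some other noncoding classes leaned lower: processed pseudogenes had 11 higher and 33 lower, and mitochondrial tRNAs 0 and 5. Genes are not independent replicates, the 2 classes were picked from 28 after seeing the counts, and without stranded counting an antisense gene shares reads with its partner. Before genomic spans were examined, genes lower in PAL were expected to have shorter spans. The reverse was found: protein-coding genes called lower spanned a median of 33.9 kb (n = 1668) and those called higher 14.3 kb (n = 1198). The difference of medians was 1.248 on the log2 scale (permutation test over genes, two-sided, p = 0.0001, the smallest that 10000 permutations can give). Genes not called spanned 35.9 kb, and with plain read totals the medians were 26.45 kb for genes called lower and 17.2 kb for genes called higher. The 165 genes that fell at least 2-fold spanned a median of 8.64 kb.

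The real split of the libraries gave 3179 changed genes, and the highest of the other splits gave 1. With 10 splits, 1 of which gave as many, the number is too small for a share under 0.05.

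Heat shock, immediate early and ATF3 genes were lower in PAL libraries. The tables argue against scaling as the cause: over the scalings tried, the heat shock list's median log2 fold change came no nearer to 0 than -0.66. HSPA6, known as nearly silent in unstressed cells, ranked 8 of 12258 genes by mean FPKM in control and 1125 in PAL, so a stress of the control cells before lysis and an exchange of the group labels both stay open, since each needs that rank. The NRF2 list, which an oxidant would raise, had a median of -0.0034, with 5 of 25 tested members lower and 1 higher. Its median was 0.062 as TPM, 0.063 with plain read totals and 0.045 after quantile normalization. The median of all genes was 0.072, 0.075 and 0.032 there, so these values show no clear rise. The list did not pass with camera (adjusted p = 0.496) but passed with fry (adjusted p = 0.0268), with members on both sides, and decides nothing. If the labels are right, PAL did not act on the control libraries, so it cannot have set the rank of HSPA6 there. As causes of the group difference, stressed control cells, exchanged labels and an effect of PAL cannot be told apart, because each coincides with the groups.

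PAL replicate 3 lay nearer to control on the first principal component (14.5 against 19.2 and 19.1), while control replicate 3, at -18.1, did not lie nearer to PAL and differed from its group in immediate early genes such as FOS. If control RNA had been mixed into PAL replicate 3, the genes at least 8 times higher in control would need 1 common share, here 3.52%. Of 13 such genes, 23.1% lay over 3 standard errors from it (EGR1 at 7.68%, JUN at 10.5% and DUSP2 at 16.8%). The others did not, such as ZFAND2A at 0.196%, HSPA6 at 2.65%, HSPA1A at 3.38%, FOSB at 3.61%, HSPA1B at 3.87% and DNAJB1 at 4.10%. This cannot decide on mixing, because it rests on 3 genes that may vary more than the spread used. A first form of this test, with an assumed noise of 5% in place of the spread between PAL replicates 1 and 2, put 46.2% over 3 standard errors away. The measured spread was a single value for all genes, here and in the test that follows. Genes that vary more, as immediate early genes did, can therefore lie beyond 3 standard errors for that reason. For PAL RNA in control replicate 3, the same test used the spread between control replicates 1 and 2. It put 36.4% of 11 genes over 3 standard errors from the common share of 19.0% (DNAJB1 at -8.45%, ATF3 at -6.05%, JUN at 42.7% and EGR1 at 48.6%). For the same reason it cannot decide on mixing, and it is the last of 3 forms tried. In the other forms, the excess of immediate early over heat shock genes was 42.0 points with genes at least 4 times higher, which argued against mixing. It was 15.2 points with genes at least 8 times higher, which left mixing open.

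Transcripts of the mitochondrial genome moved both ways. Scaling does not account for this: at least 3 protein-coding genes were called in each direction under every scaling tried. Weaker poly-A selection in PAL libraries would raise MT-ND6, which lacks a long poly-A tail, and histone transcripts together with both ribosomal RNAs: MT-ND6 changed by -0.79 but is itself a light-strand gene, and of 15 histones 5 were higher and 4 lower, so this stays open and cannot be told apart from a change of the transcripts, whereas a first form of the test, on MT-ND6 alone, would have argued against it. A hypothesis is that light-strand transcripts fell more: the 8 tested genes on that strand differed on average by -1.018 from the 22 on the heavy strand (permutation test over genes, two-sided, p = 0.0139). With at least 60 reads over the 6 libraries the difference was -0.96 for 5 against 15 genes (permutation p = 7.10e-04). That minimum left out MT-TT of the heavy strand, which had the largest fitted fall (-4.20), so the lower p is no separate support. Genes of the mitochondrial genome are not independent replicates. Many of the tested ones are tRNA genes with few reads, MT-TT on the heavy strand went from 53 reads in control to 0 in PAL (at least 20.49-fold lower, floor of 3 reads over the group), and strand was not stated for the counting, so no biological explanation was tested.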
